A study of Homo sapiens with 13 samples.

How the data were processed

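Gene expression was measured with Affymetrix human genome oligonucleotide arrays, 1 array per sample, in 13 samples taken at the diagnosis of biphenotypic leukemia. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled complementary RNA was made by in vitro transcription. The labels put all samples in 1 group and describe the material as marrow aspirate or blood without saying which of these a sample was. The samples were not described as sorted, so normal blood cells could contribute RNA to any of them.

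The deposited table holds 1 signal intensity per probe set and array on a linear scale, which the submitters' processing notes credit to MAS5, an algorithm that combines the perfect-match and mismatch probes of a probe set. Its version and scaling target are not given in the sources used here. From the values, the arrays had been brought to nearly the same mean: the mean of the central 96% of probe sets lay between 539 and 567 in the 13 arrays. All values were above 0. The table as used here held 16383 probe sets, which is part of the array, and genes without a probe set in it were not analysed here. It held no AFFX control probe sets, so the planned 3-prime to 5-prime ratios of GAPDH and ACTB were not run. The columns came in 2 formats, with values rounded to 3 significant digits in 8 samples and to 1 decimal in 5 samples. What the formats stand for is not given in the sources used here, and they were treated as a possible batch.

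Probe sets were named through the platform annotation. Of the 16383 probe sets, 14045 had 1 gene symbol, 792 had several and 1546 had none. Only probe sets with 1 symbol were named, which gave 8549 genes. Because the donors are patients, 154 of the probe sets with 1 symbol were left out of every step on genes, lists and components, and a further 56 with several symbols. These were for genes tied to sex, HLA genes, antigen receptor variable segments and genes with common germline expression polymorphisms. Only the signal summaries of each array and the correlations between arrays were taken over all probe sets. Signals were kept on the deposited scaling, raised to a floor of 61.9 (the 25th percentile of all remaining values) and put on the log2 scale. Each gene was represented by its probe set with the highest mean, giving 8459 genes. Genes were kept when at least 3 of the 13 samples lay above the pooled median of 223, which left 5783 genes. A value at the floor has no order against another such value, and a ratio to it is given as "at least".

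With 1 group there was no contrast between groups, and the design gives the spread between patients and the relations between gene programmes. Before the data were examined, 18 gene lists with 383 genes, the tests, the rule for naming genes and most alternative settings were fixed. Of the list genes, 296 had a probe set and 248 passed the filter. For each list, the median over its genes of the SD across samples, and the mean pairwise Spearman correlation between its genes, were set against 10000 random lists of the same size drawn from 20 bins of mean expression. A list above the 95th percentile was called widely spread or jointly varying, as a description of these samples with no p-value across genes. A list score is the mean over its genes of the log2 signal minus the gene's mean. Relations between scores were given as Pearson's r and Spearman's rho with two-sided permutation p-values (100000 resamples, or exact permutation in 8 samples), with Benjamini-Hochberg adjustment within each family, and r was given again without the 2 samples farthest from the median of the first measure. No pooled r was computed where scores split into separate clusters, defined as a largest gap above 0.334 of the range with at least 2 samples on either side, which normal samples of this size exceed in 5% of draws. Enrichment among the 200 genes with the largest SD, and among the 200 genes at each end of a principal component of the 1000 most variable genes, was tested by one-sided Fisher's exact tests with Benjamini-Hochberg adjustment; genes are not independent, so these p-values are too small. Component shares were set against 100 data sets in which each gene was permuted over samples.

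Genes named in the text are, for each list, up to 5 kept genes with the largest SD and the 2 with the smallest, the 20 genes of the array with the largest SD, and the 5 genes at each end of components 1 and 2. This gave 133 genes. Of these, 54 had several probe sets, and in 25 of the 54 another probe set correlated with the chosen one at r under 0.5.

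The procedure was tested on simulated data with 5783 genes and 13 samples. When a shared factor with an SD of 1 log2 unit was planted in a list, 98.3% of planted lists were called widely spread and 100% jointly varying, against 4.58% and 5.83% of lists without a factor. With a factor SD of 0.5, the shares of planted lists were 61.7% and 100%. The simulated noise was normal and independent between genes, with no floor. These rates, and the recoveries that follow, may not hold for genes at the floor or correlated genes. A correlation of -0.8 was planted between the factors of the B and T lineage lists only. With a factor SD of 1 it was recovered after adjustment in 12 of 20 simulations. With a factor SD of 0.5 and 0.25 it was recovered in 6 and 1 of 20, so a relation that missed the threshold is not shown to be absent. The number of arrays limits the precision.

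Alternatives covered the scaling (array median, quantile), the floor, the expression filter, the probe set per gene, the list score, the measures and thresholds, and leaving out each sample in turn. After the data had been seen, alternatives by column format and without samples that stood apart were added. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.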

Results

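The data comprised 13 arrays from diagnostic samples of biphenotypic leukemia, an acute leukemia whose cells carry features of more than 1 blood lineage. The labels gave 1 group of 13 patients and no subtype, so the questions open to these data were how far lineage programmes differed between patients and which programmes went together. The median signal of an array lay between 189 and 290.5, and 20.6% to 28.2% of probe sets were at the floor. Spearman correlations between arrays over all probe sets ran from 0.779 to 0.902 over 78 pairs, with a median of 0.850, and no 2 arrays held identical values.

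Genes of the blood lineages were among the most variable of the array. The gene with the largest SD was AZU1, a protein of neutrophil granules, at a mean log2 signal of 9.55 ± 2.87 (SD, n = 13), followed by CXCL8, a chemokine that attracts neutrophils (9.94 ± 2.73), and ELANE, neutrophil elastase (9.81 ± 2.68). IGFBP7, a secreted protein that binds insulin-like growth factors, had an SD of 2.58, and the cytokine IL32 had an SD of 2.55. Of 5783 genes, 764 (13.2%) had an SD above 1 log2 unit, and the median SD was 0.57. Of 18 gene lists, 12 were widely spread, 14 varied jointly, and 9 were enriched among the 200 genes with the largest SD after adjustment by Fisher's exact test. The count of genes with SD above 1 fell to 295 when the floor was raised to the pooled median.

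**Figure D1:**
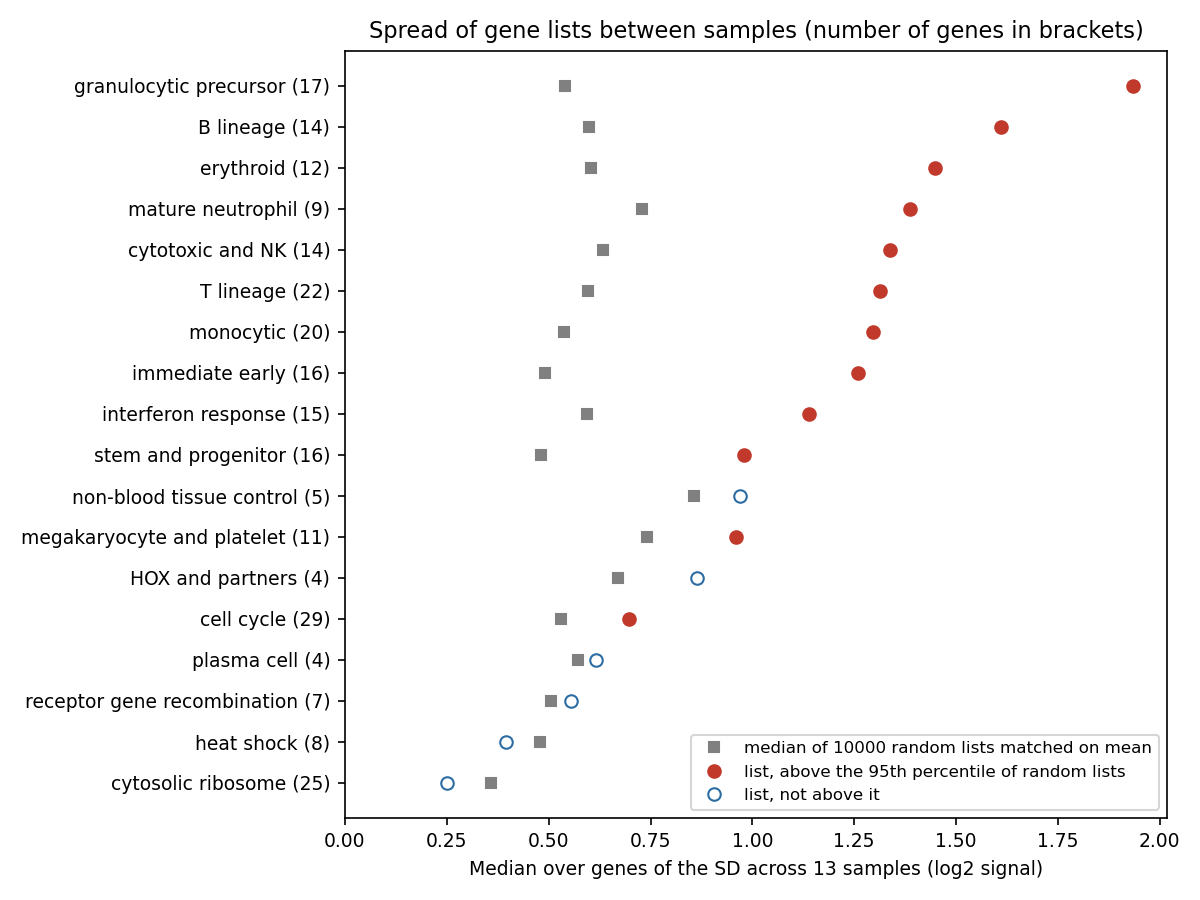
Spread of the 18 gene lists between 13 samples. The x axis is the median over a list's genes of the SD of log2 signal, circles are the lists (filled where above the 95th percentile of random lists), and squares are the median of 10000 random lists matched on mean signal; the granulocytic precursor list lies farthest right at 1.93 and the cytosolic ribosome list farthest left at 0.25.

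Granulocytic precursor genes differed most between patients. MPO, the myeloperoxidase whose presence in blasts marks the myeloid lineage, ran from a signal of 92.9 to 44400 (478-fold), at a mean log2 signal of 12.48 ± 2.42 (SD, n = 13). The granule proteases ELANE, AZU1 and PRTN3 were at the floor in 2 samples each and reached 18510, 24312 and 14268, at least 299-fold, 393-fold and 230-fold above it. PRG2, a protein of eosinophil granules, was at the floor in 4 samples and reached 8900. At the other end of this list, CEBPA, a transcription factor of myeloid differentiation, had an SD of 1.04, and CSF3R, the receptor for granulocyte colony-stimulating factor, had an SD of 0.99. Of the 17 genes, 16 had an SD above 1, the median SD was 1.93 (percentile 100 of matched random lists), the mean pairwise rho was 0.343 (percentile 100), and 13 genes were among the 200 most variable (0.588 expected, Fisher's adjusted p = 2.61e-15).

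Monocytic genes were also widely spread. CD14, a receptor for bacterial lipopolysaccharide on monocytes, was at the floor in 4 samples and reached 2750, at least 44.4-fold higher. The calcium-binding proteins S100A8 and S100A9 ran from 1007 to 42137 and from 310 to 13661, and S100A12 and MNDA had SDs of 1.71 and 1.68. The smallest spread of the list was that of CTSS, a lysosomal protease, with an SD of 0.52. Another probe set of CTSS correlated with the chosen one at r = 0.342. The median SD of the 20 genes was 1.30 (percentile 100), the mean pairwise rho was 0.261 (percentile 100), and 8 genes were among the 200 most variable (0.692 expected, Fisher's adjusted p = 9.42e-07).

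B lineage genes were spread over a similar range. IGLL1, a surrogate light chain of precursor B cells, had a mean log2 signal of 9.83 ± 2.33 (SD, n = 13) and reached at least 203 times the floor. CD9, a surface protein of B precursors and other cells, had an SD of 2.12, the adaptor BLNK of B cell receptor signalling 1.84, the immunoglobulin heavy chain gene IGHM 1.73, and TCL1A, a kinase coactivator of early B cells, 1.69. The smallest SDs were those of SPIB (0.71) and BLK (0.53). Of the 14 genes, 12 had an SD above 1, the median SD was 1.61 (percentile 100), the mean pairwise rho was 0.446 (percentile 100), and 9 were among the 200 most variable (0.484 expected, Fisher's adjusted p = 9.19e-10). Another probe set of IGHM correlated with the chosen one at only r = 0.468 across the 13 samples, and that of BLK at r = 0.04, so the values of these genes depend on the probe set.

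T lineage genes were widely spread as well. CD3D, a chain of the T cell receptor complex, ran from 367 to 8620 (23.5-fold) around a median of 6200, at a mean log2 signal of 11.26 ± 2.02 (SD, n = 13). The kinase LCK, which starts T cell receptor signalling, was at the floor in 2 samples and reached 3001, and CD7, an early T and NK cell surface protein, was at the floor in 2 samples and reached 2900. GATA3, a transcription factor of T cell development, had an SD of 1.80, and the surface receptor CD96 had an SD of 1.74. By contrast CD1A, a marker of cortical thymocytes, had an SD of 0.59, and PTCRA, the pre-T cell receptor chain, an SD of 0.37; another probe set of PTCRA correlated with the chosen one at r = -0.105. Of the 22 genes, 15 had an SD above 1, the median SD was 1.31 (percentile 100), the mean pairwise rho was 0.271 (percentile 100), and 8 were among the 200 most variable (0.761 expected, Fisher's adjusted p = 1.69e-06).

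**Figure D2:**
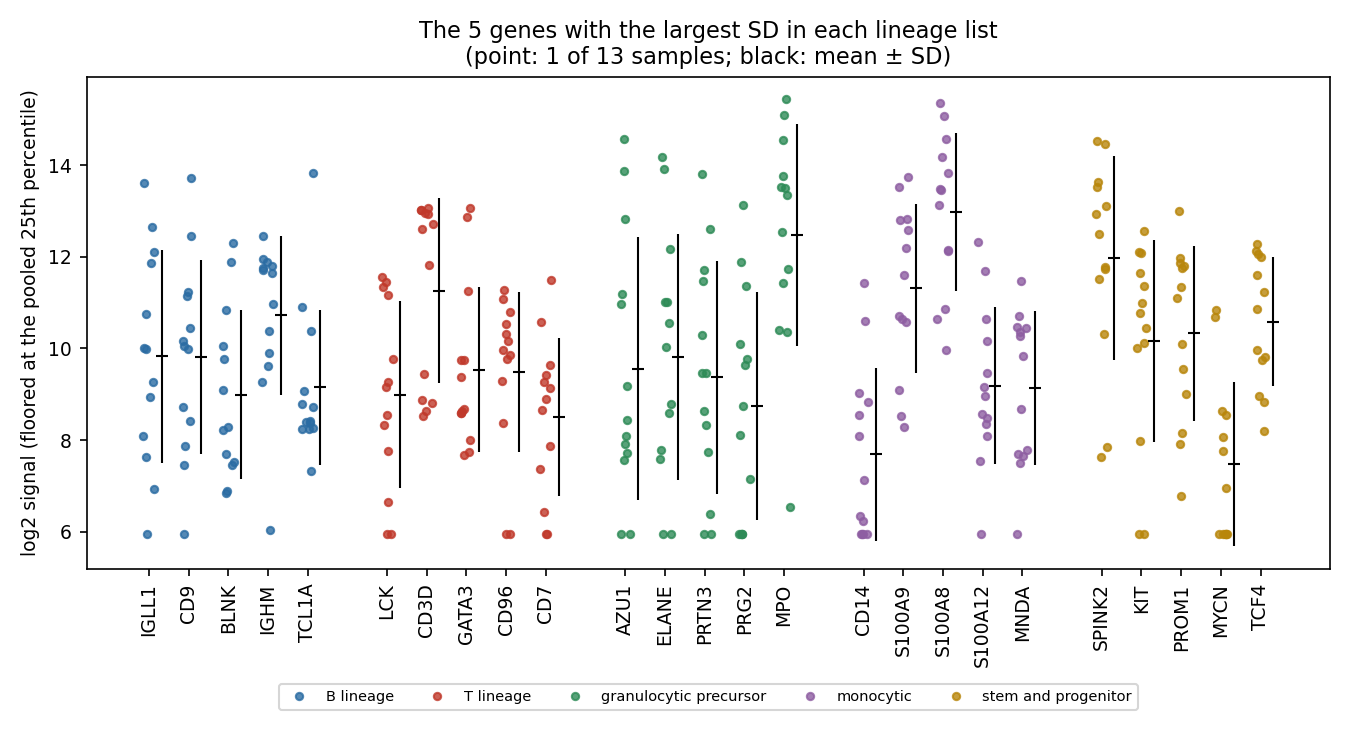
The 5 genes with the largest SD in each of 5 lineage lists. The y axis is log2 signal with the floor applied, each point is 1 of 13 samples, and black bars are the mean ± SD; MPO spans signals of 92.9 to 44400 and CD3D signals of 367 to 8620.

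Stem and progenitor genes were widely spread as single genes and did not vary jointly. SPINK2, a protease inhibitor of primitive hematopoietic cells, ran from 198 to 23600 (119-fold), and the receptor KIT was at the floor in 2 samples and reached 6077. PROM1, a surface protein of progenitors, had an SD of 1.90, the transcription factor MYCN 1.80 with 6 samples at the floor, and the transcription factor TCF4 1.41. The regulators MYB and LMO2 were high in all samples, with lowest signals of 3120 and 1930 and SDs of 0.55 and 0.50. Another probe set of MYB correlated with the chosen one at r = 0.362. The median SD of the 16 genes was 0.98 (percentile 100), and the mean pairwise rho was 0.07 (percentile 94.2), a position that moved above the 95th percentile in 10 of 27 alternatives. Of the HOX genes and their partners, 4 were kept, and no gene of the HOXA cluster was analysed here. MEIS1, a HOX cofactor, had an SD of 1.35 and PBX3 an SD of 1.05; the list was not called widely spread (percentile 88.4), except with the mean of all probe sets and without probe sets that can match several transcripts (both percentile 97.1).

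Among the genes of antigen receptor recombination, DNTT, the terminal transferase of immature lymphocytes, stood out with a mean log2 signal of 10.86 ± 2.09 (SD, n = 13) and a reach of at least 99.1-fold above the floor. The DNA end-joining genes of the list varied less, with SDs of 0.90 for LIG4, 0.42 for XRCC5, 0.37 for PRKDC and 0.34 for XRCC6. Another probe set of PRKDC correlated with the chosen one at r = 0.232, and another of XRCC6 at r = -0.307, so the values of these 2 genes depend on the probe set. RAG1 and RAG2, the recombinase genes, did not pass the filter (highest signals 342 and 219). The list and its score therefore held DNTT, ADA and genes of DNA end joining. The 7 kept genes had a median SD of 0.55 (percentile 66.6). Their mean pairwise rho of 0.188 (percentile 98.7) lost its call in 7 of 27 alternatives.

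Whether lineage programmes excluded or accompanied one another was asked over 15 pairs of the B, T, granulocytic precursor, monocytic, stem and progenitor, and recombination scores. No pair passed the adjusted permutation test, and no pair had an unadjusted p under 0.05. B and T lineage scores had r = -0.443 (permutation p = 0.129, adjusted p = 0.484) and rho = -0.390 (p = 0.189), and r = -0.241 without the 2 samples farthest out. T lineage and granulocytic precursor scores had r = -0.470 (permutation p = 0.106, adjusted p = 0.484) and rho = -0.445 (p = 0.131), with r = -0.231 without the 2 farthest samples. The lowest r, -0.489 (permutation p = 0.0909, adjusted p = 0.484; rho = -0.555, p = 0.0522), was that of monocytic with stem and progenitor scores; without the 2 farthest samples it was -0.447. B lineage and recombination scores had r = -0.04 (permutation p = 0.904, with rho = -0.08, p = 0.806). Without the 2 farthest samples r became -0.801 (permutation p = 0.00299, not adjusted over the pairs). Within the 8 samples of 1 column format r was 0.107 (exact permutation p = 0.804). Without the 2 farthest of those 8 it was -0.606 (exact permutation p = 0.196). Within the same 8 samples, r was -0.309 for B with T lineage (exact permutation p = 0.458). It was -0.500 for T lineage with granulocytic precursor (p = 0.211) and -0.344 for monocytic with stem and progenitor scores (p = 0.406). The 5 samples of the other format were too few. A correlation of -0.8 planted between the B and T lineage lists was recovered in 12 of 20 simulations at a factor SD of 1 and 6 of 20 at 0.5. No correlation was planted in other pairs, so recovery there is not known. The stem and progenitor (0.43) and recombination (0.41) lists had small score SDs, but a score SD is not the same measure as a factor SD. Opposing programmes were not excluded.

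**Figure D3:**
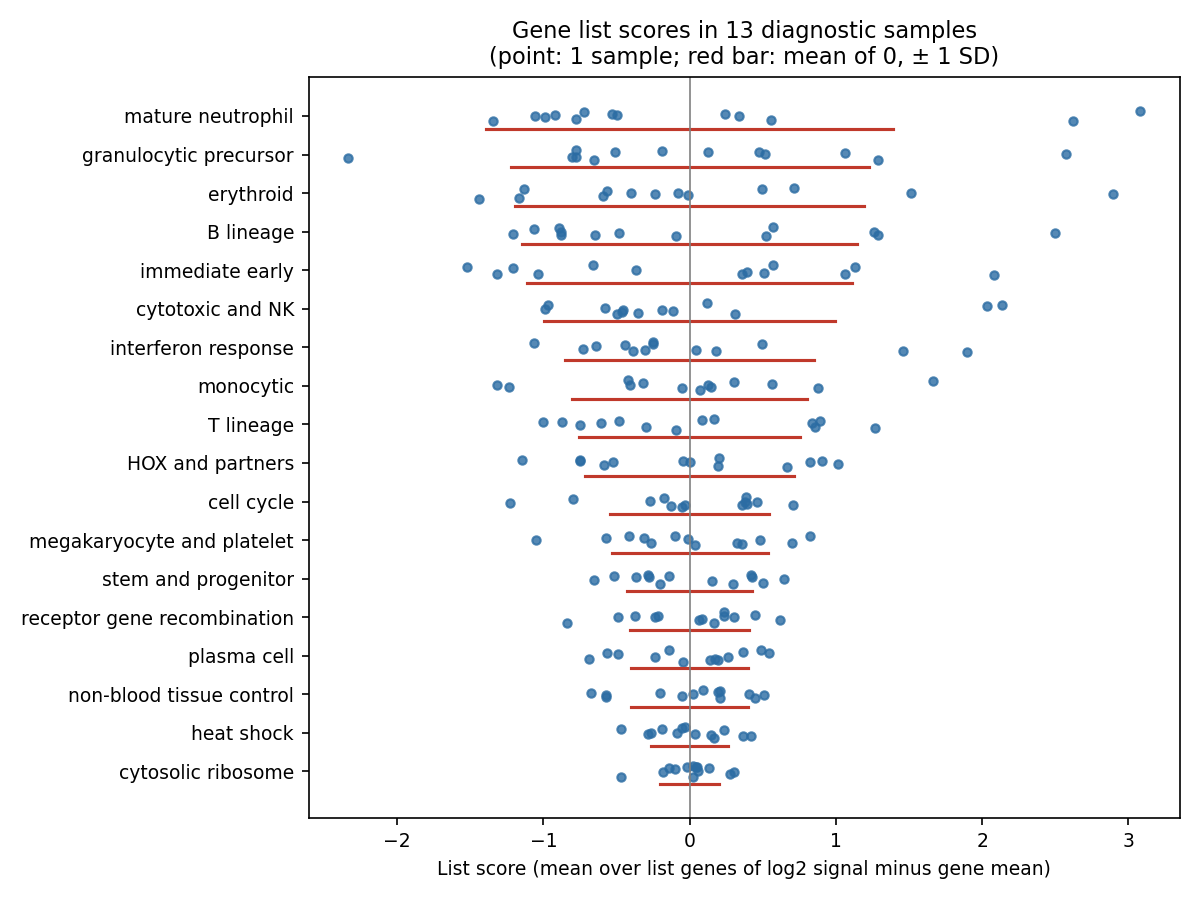
Scores of the 18 gene lists in 13 samples. The x axis is the mean over a list's genes of log2 signal minus the gene's mean, each point is 1 sample, and red bars are ± 1 SD around the mean of 0; the granulocytic precursor scores run from -2.33 to 2.58, and 2 samples stand apart on the cytotoxic and NK list and 2 on the mature neutrophil list.

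Genes of other blood cells varied between the samples too. Erythroid genes formed 1 of the most jointly varying lists: ALAS2, the first enzyme of heme synthesis in red cell precursors, was at the floor in 3 samples and reached 15000, at least 242-fold higher, and the globin HBD ran from 1120 to 59100. The 12 erythroid genes had a median SD of 1.45 (percentile 100) and a mean pairwise rho of 0.574 (percentile 100). Among the cytotoxic and NK genes, the granzyme GZMA reached 3810 from the floor (at least 61.6-fold), the pore-forming PRF1 ran from 160 to 7680, and GNLY, a granule protein, from 104 to 3710; the list's median SD was 1.34 (percentile 100). Of the mature neutrophil genes, LTF, lactoferrin, was at the floor in 8 samples and reached 6780, and CEACAM8 was at the floor in 3 and reached 4461. The median SD of the 9 kept genes was 1.39 (percentile 99.99). CXCR1 and CXCR2 did not pass the filter (highest signals 309 and 130), and FCGR3B and CD177 were not analysed here. The score therefore rested on other genes of the list, such as LTF, CAMP, LCN2 and CEACAM8. A high score does not by itself show mature neutrophils. The 11 megakaryocyte and platelet genes, with PPBP at the floor in 7 samples and SPARC at an SD of 1.32, had a median SD of 0.96 (percentile 98.1), a call lost in 18 of 27 alternatives. Another probe set of SPARC correlated with the chosen one at r = 0.303. The 4 plasma cell genes were not widely spread (percentile 61.0); JCHAIN had an SD of 0.94 and XBP1 an SD of 0.35.

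On the cytotoxic list and on the mature neutrophil list, 2 samples each lay above a gap of 0.552 and 0.467 of the range, so no pooled r was given for 12 of the 72 pairs of lineage lists with other lists. Without the 2 samples apart on the cytotoxic list, the cytotoxic list's median SD was 0.80 (percentile 93.0) and that of the T lineage list was 1.10 (percentile 100). Leaving out single samples, the relation of T lineage with cytotoxic scores passed the rule on clusters in 1 of 13 cases, with r = 0.831 (permutation p = 2e-05, adjusted p = 0.001; rho = 0.881, p = 0.00034), with r = 0.821 without the 2 farthest samples. In that case 1 sample still stood apart on the cytotoxic list, by 0.553 of the range, and the scores split again once it was left out too. With all 13 samples this relation could not be tested.

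Of the 60 pairs that could be tested, none passed the adjusted permutation test and 4 had an unadjusted p under 0.05. B lineage and interferon response scores had r = 0.725 (permutation p = 0.00674, adjusted p = 0.396) and rho = 0.544 (p = 0.0576); r was 0.668 without the 2 farthest samples and 0.805 within the 8 samples of 1 format (exact permutation p = 0.0157). It was 0.508 without 1 sample (permutation p = 0.0876). Without the 2 samples farthest out on component 1 it was 0.208 (permutation p = 0.540), so 1 or 2 samples carried much of it. The largest gap of the interferon scores was 0.326 of the range, close to the limit of 0.334 for separate clusters. Under several alternatives the rule on clusters left this pair untested. These included array median scaling, the raised floor, the mean filter, scores from unit SD genes and scores from the median over genes. Recombination and cell cycle scores had r = 0.634 (permutation p = 0.0198, adjusted p = 0.396) and rho = 0.522 (p = 0.0708), but r = 0.185 without the 2 farthest samples, and r = 0.448 within the 8 samples (exact permutation p = 0.269). This pair passed the test when genes were scaled to unit SD in the scores (r = 0.861, adjusted p = 0.0115), when the score was the median over genes (r = 0.844, adjusted p = 0.0157), and when 1 sample was left out (r = 0.838, adjusted p = 0.0277). It lost the unadjusted p under 0.05 with the mean filter (r = 0.501, permutation p = 0.0823), the mean of all probe sets (r = 0.453, p = 0.119), without probe sets that can match several transcripts (r = 0.475, p = 0.103), without either of 2 other samples (r = 0.514 and 0.558, p = 0.0845 and 0.0601), and without the 2 samples farthest out on component 1 (r = 0.540, p = 0.0888). In the 3 settings that passed, r without the 2 farthest samples was 0.649, 0.767 and 0.680. Recombination and megakaryocyte scores had r = -0.656 (permutation p = 0.0149, adjusted p = 0.396; rho = -0.462, p = 0.114), r = -0.638 without the 2 farthest samples and r = -0.907 within the 8 samples (exact permutation p = 0.00221); with another sample left out the adjusted p was 0.0492. Granulocytic precursor and erythroid scores had r = -0.579 (permutation p = 0.0419, adjusted p = 0.515; rho = -0.346, p = 0.246), -0.06 without the 2 farthest samples and -0.508 within the 8 samples (exact permutation p = 0.200).

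Genes of the immediate early response, transcription factors and regulators induced within minutes of a stimulus, rose and fell together across samples. The nuclear receptors NR4A2 and NR4A1 were at the floor in 3 and 6 samples and reached 9850 and 7130, at least 159-fold and 115-fold higher. JUN reached at least 68.0 times the floor, ATF3 ran from 102 to 6100, and FOSB ran from 132 to 5398. The smallest SDs were those of IER2 (0.81) and JUND (0.70). The 16 genes had a median SD of 1.26 (percentile 100) and a mean pairwise rho of 0.638, the highest of the 18 lists (percentile 100). Of these genes, 5 were among the 200 most variable (0.553 expected, Fisher's adjusted p = 0.000343). Outside the list, HBEGF, a growth factor, had an SD of 2.37, RGS1, a regulator of G protein signalling, 2.36, and the kinase SIK1 2.32. Another probe set of NR4A1 correlated with the chosen one at r = 0.317.

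Interferon response genes were widely spread, with a median SD of 1.14 over 15 genes (percentile 100) and a mean pairwise rho of 0.438 (percentile 100). IFI44L was at the floor in 8 samples and reached 5790, and MX1, an antiviral GTPase, ran from 297 to 7560. The spread call was lost with the median absolute deviation (percentile 83.6) and without the 2 samples farthest out on component 1 (percentile 91.9). Cell cycle genes varied jointly (29 genes, mean pairwise rho 0.511, percentile 100) over a smaller range, with a median SD of 0.70 (percentile 99.4, but 94.5 without the 2 samples apart on the cytotoxic list, which ended the call); TOP2A, a topoisomerase of dividing cells, ran from 102 to 1730 and MKI67 from 359 to 910. Heat shock genes were not widely spread (8 genes, median SD 0.40, percentile 15.7), although HSPB1 had an SD of 1.44. Cytosolic ribosome genes had the smallest spread (25 genes, median SD 0.25, percentile 0), with RPL32 between 33284 and 47400 in all samples. They were still called jointly varying (mean pairwise rho 0.479, percentile 100), so a joint call does not require a wide spread. The 5 kept genes of the control list for non-blood tissues were neither widely spread (percentile 82.3) nor jointly varying (percentile 47.3). They were called widely spread with the median absolute deviation (percentile 97.2). Their median SD was 0.97, against 0.86 in matched random lists. FGA and TNNI3 each had an SD of 1.03, with 3 and 4 samples at the floor. An SD near 1 at low signal was thus also seen in genes chosen for other tissues.

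Without reference to lists, 4 principal components exceeded the highest share in permuted data (2 to 5 over the alternatives). They held 19.3%, 16.5%, 11.2% and 9.57% of the variance, against 10.7%, 10.1%, 9.71% and 9.24%. At the high end of component 1 lay 13 of 14 immediate early genes (Fisher's adjusted p = 2.33e-07) and 11 of 12 B lineage genes (adjusted p = 2.75e-06), and at its low end 10 of 17 T lineage genes (adjusted p = 0.00493) and 7 of 12 cytotoxic genes (adjusted p = 0.0313). HBEGF, NR4A1, ID2, CD9 and PPP1R16B led the high end, and SPINK2, AKR1C3, CD96, KIT and IL32 the low end. At the high end of component 2 lay 14 of 17 granulocytic precursor genes (adjusted p = 1.46e-06) and 6 of 8 mature neutrophil genes (adjusted p = 0.00995), led by AZU1, ELANE, MPO, PRTN3 and DNTT. At its low end lay 9 of 12 cytotoxic genes (adjusted p = 0.000935), 7 of 10 erythroid genes (adjusted p = 0.00915) and 7 of 12 B lineage genes (adjusted p = 0.0251), with CX3CR1, HPGD, GZMA, TNFSF10 and LCK leading. Sample scores on component 2 split into separate clusters: 2 samples lay at -35.6 and -26.3, and the next at -5.16. They were the 2 samples apart on the cytotoxic list, with erythroid scores of 2.90 and -1.13. This end therefore mainly set 2 samples apart from the others. Component 3 held all 10 erythroid genes (adjusted p = 2.9e-06) and 11 of 17 T lineage genes (adjusted p = 0.00109) at 1 end. Over 28 alternatives, the calls on component 1 held on that component in 28 for the B lineage, 26 for the immediate early, 24 for the T lineage and 14 for the cytotoxic list. On component 2 they held in 25 for the granulocytic precursor and cytotoxic lists, 18 for the erythroid and B lineage lists and 12 for the mature neutrophil list, and on component 3 in 24 for the erythroid and 20 for the T lineage list. With 1 sample left out, the highest adjusted p by Fisher's exact test was 0.0251 for the B lineage, 0.0911 for the immediate early, 0.0584 for the T lineage and 1 for the cytotoxic list on component 1. On component 2 it was 0.453 for the granulocytic precursor, 0.480 for the cytotoxic, 0.108 for the erythroid, 0.632 for the B lineage and 1 for the mature neutrophil list, and on component 3 it was 0.688 for the erythroid and 1 for the T lineage list. A list that lost its place on 1 component could lead another, and the mature neutrophil list was called on any of the first 3 in 16 of 28.

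**Figure D4:**
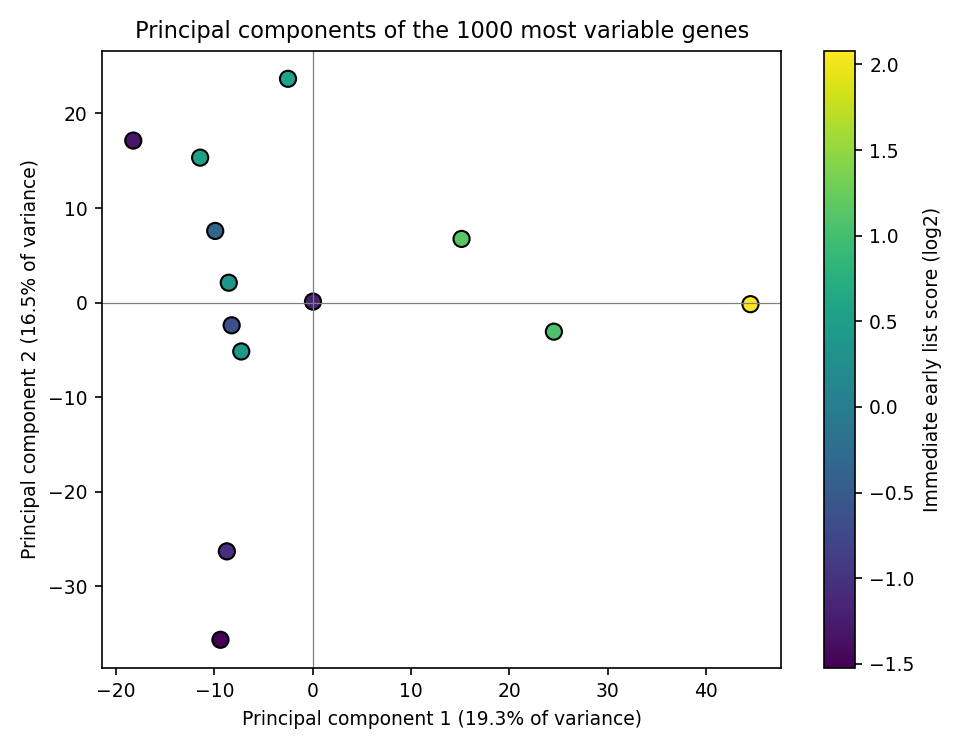
The 13 samples on the first 2 principal components of the 1000 most variable genes. The axes are component scores with their shares of variance (19.3% and 16.5%), each point is 1 sample, and the colour is its immediate early list score in log2 units.

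Array measures and column format were set against the same scores. Of 36 relations of list scores and components with the share of probe sets at the floor or the median signal, none passed the adjusted permutation test and 3 had an unadjusted p under 0.05; 6 further pairs were not tested because of clusters. The lowest p was that of heat shock scores with the median signal (r = -0.701, permutation p = 0.00732, adjusted p = 0.264; rho = -0.648, p = 0.0193), with r = -0.409 without the 2 farthest samples and r = -0.643 within the 8 samples of 1 format (exact permutation p = 0.0836). This relation passed the test in 3 alternatives: without the 2 samples apart on the cytotoxic list (r = -0.897, adjusted p = 0.00342), without 1 sample (r = -0.815, adjusted p = 0.0380) and with the floor at the pooled median (r = -0.736, adjusted p = 0.0439). In the first 2 of these, heat shock scores also passed with the share at the floor (r = 0.902 and 0.792, adjusted p = 0.00342 and 0.0439). With the raised floor, the non-blood control list passed with the share at the floor (r = -0.846, adjusted p = 0.00748) and the median signal (r = 0.769, adjusted p = 0.0355). Between the column formats, no mean of the 23 measures differed at an unadjusted p under 0.05 by exact permutation over 1287 splits. The lowest adjusted p was 0.708. Spread was not tested. The SD was 21.9 in the 8 samples and 4.64 in the 5 for component 1, and 1.28 and 0.335 for cytotoxic scores. It went the other way for granulocytic precursor (1.02 and 1.41) and mature neutrophil scores (1.29 and 1.68). The 2 samples apart on the cytotoxic list and the 2 farthest out on component 1 were all among the 8. A tie of format to spread is not excluded.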

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

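Alternatives by column format and those leaving out 2 samples that stood apart were added only after the data were seen; the others were planned. The count of 0 relations between lineage lists held in all 28 alternatives. Widely spread lists numbered 9 to 12, jointly varying lists 12 to 16 and lists enriched among the 200 most variable genes 7 to 10 over 27 alternatives each, and component 1 held 17.6% to 30.1% of the variance over 28. The B, T, granulocytic precursor, monocytic, stem and progenitor, and immediate early lists kept their spread and enrichment calls in all 27 alternatives; enrichment of the erythroid, cytotoxic and mature neutrophil lists held in 25, 26 and 24. The count of genes with SD above 1 (764) was 295 with the floor at the pooled median and 164 with the threshold at an SD of 1.5; both follow from the construction; it was 1092 with no floor. Relations of lineage lists with other lists past the adjusted test numbered 0 in all 13 samples, 1 with unit SD genes in scores, 1 with the median over members in scores, and 0 to 2 with each sample left out in turn. Relations with array measures numbered 0, but 3 with the floor at the pooled median, 0 to 2 with each sample left out, and 2 without the 2 samples apart on the cytotoxic list. The cause of these changes was not tested. Signals near the floor limit genes such as PPBP, LTF and IFI44L, whose lower levels are only bounds. RNA integrity measures from control probe sets were not run.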

Other observations

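The tests of column format on the immediate early genes, of the 2 farthest samples on component 1 and of the T lineage with the cytotoxic scores were chosen only after the results they measure were seen. The tests without the 2 samples apart on the cytotoxic or mature neutrophil list used settings added after the data were seen, as did the test of spread without the 2 samples farthest out, but what each would show was written down before its result. The weighing covers 3 patterns, and the labels give no groups, so no biological explanation was tested against a design.

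Genes outside the lists with a large SD included CFD, complement factor D, at a mean log2 signal of 8.82 ± 2.27 (SD, n = 13), S100P, a calcium-binding protein, at 8.24 ± 2.26, and GJA1, a gap junction protein, which was at the floor in 7 samples and reached 2310. At the low end of component 2, CX3CR1, a chemokine receptor of cytotoxic lymphocytes and some monocytes, reached at least 112 times the floor, and HPGD, a prostaglandin-degrading enzyme, ran from 71 to 4360. At the ends of component 1, ID2, an inhibitor of transcription factors, reached at least 271 times the floor, and AKR1C3, an aldo-keto reductase, at least 48.1 times. No test was run on these genes singly.

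The immediate early genes differed widely between samples. A difference between the column formats was argued against, since the list lay at percentile 100 of matched random lists within the 8 samples of 1 format (median SD 1.49). The 2 samples farthest out on component 1 were argued against as the whole source, since without them the list lay at percentile 100 (median SD 1.13). These genes are known to be induced when blood or marrow is handled or stored before RNA extraction, and handling may differ between samples; with no record of handling times used here, this stays open beside signalling in the leukemic cells.

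The lead of the immediate early genes at 1 end of component 1 was weighed separately. Array scaling was argued against as the whole source, since after quantile normalization 9 of 13 genes of the list lay among the 200 at the better end (Fisher's adjusted p = 0.00228). With array median scaling it was 12 of 14 (Fisher's adjusted p = 3.09e-06). On the deposited scaling it was 13 of 14 (Fisher's adjusted p = 2.33e-07), so a part played by scaling is not excluded. The 2 samples farthest out on principal component 1 could account for it: without the 2 samples, 6 of 12 genes lay there (adjusted p = 0.0911), and leaving out only the farthest gave the same counts. The list then reached an adjusted p of 0.0313 on another of the first 3 components. B lineage and immediate early scores had r = 0.254 (permutation p = 0.406) and rho = 0.104 (p = 0.737) over the 13 samples, and r = 0.317 without the 2 farthest samples (p = 0.339). Within the 8 samples of 1 column format r was 0.654 (exact permutation p = 0.0772, adjusted p = 0.514), so a joint rise of these lists was not shown. T lineage and immediate early scores had r = -0.446 over the 13 samples (permutation p = 0.126) and -0.807 within the 8 samples (exact permutation p = 0.0181, adjusted p = 0.361).

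Lineage genes differed between samples, which normal cells mixed into unsorted blood or marrow might produce. The 2 samples that stand apart on the cytotoxic list were argued against as the whole source of the T lineage spread, since without them the T lineage list stayed at percentile 100 with a median SD of 1.10. Likewise the granulocytic precursor list stayed at percentile 100 with a median SD of 1.58 without the 2 samples that stand apart on the mature neutrophil list. The cytotoxic list fell to 0.80 and the mature neutrophil list to 1.07 without their own 2 samples. Both falls follow from how these samples were picked and add nothing to the argument. Admixed cytotoxic T and NK cells in varying amounts stay open: the scores of T lineage and cytotoxic lists had r = 0.831 over 12 samples, and without both samples apart the scores split into clusters (a gap of 0.439 of the range against a limit of 0.376), so no pooled r is given there; the levels of NKG7 (721 to 4490) and GNLY (104 to 3710) do not decide. Leukemic cells that themselves express T and NK genes would give the same relation, and the 2 readings cannot be told apart here.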
